A study of Homo sapiens with 17 samples.

How the data were processed

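Gene expression was measured by RNA sequencing (TruSeq stranded mRNA libraries) in 17 samples of human mammary epithelial cells, 5 infected with an adenovirus carrying ERBB2 and 12 with one carrying green fluorescent protein (GFP), all for 18 hours at a multiplicity of infection of 500. Groups and replicate numbers were taken from the sample labels, and sequencing lane and index from the library names in the deposited files.

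The submitters' notes list FastQC, featureCounts, edgeR and limma with the hg19 build, without versions. The aligner, the gene annotation, the strand setting of the counting and the handling of reads that fit several genes are not given in the sources used here, so values of overlapping, antisense and near-identical genes are uncertain. The authors made raw read counts per gene for each library with featureCounts, as deposited, 1 table per library. The authors also deposited FPKM (fragments per kilobase and per 1000000 fragments) and TPM, which sum to 1000000 in every library. A table deposited under the name of a second pipeline holds expected counts per gene, that is, estimated counts with some fractions, whose quantification tool and annotation were not stated. A second table of that pipeline holds a normalised signal, which the authors, per the deposited values, made by dividing the expected counts by 1 factor per library, which gave all libraries nearly the same upper quartile. A deposited table of all counts was checked against the 17 count tables and held the same values for the 23367 genes they share. The tables of FPKM and TPM for all libraries together were not used, since they repeat the values per library.

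The count tables held 23368 genes. Total counts per library ran from 13.5 M to 25.1 M (M stands for 1000000). Intervals and floors cover counting error only, since the reads carry no molecular identifiers. Where a group held 0 counts, its floor was taken as 3 counts over the group. Gene positions came from GENCODE 44 lifted to GRCh37, matched by symbol for 19556 genes and by an older symbol for 1935.

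Counts were analysed in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM scaling, quasi-likelihood F-test), with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM are counts per 1000000 after TMM scaling, and log2 CPM used a prior count of 2. Lists of genes, 33 in all, and the main choices were fixed before the data were examined. Each list was tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. A list score was the mean over its genes of log2 CPM minus the mean of the GFP libraries, compared by two-sided exact permutation tests. The sequencing lane could not enter the fit, because HER2 was in lane 4 alone and GFP in lanes 1 and 2. The GFP libraries of lane 2 were therefore compared with those of lane 1, and HER2 with the GFP libraries of either lane.

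ERBB2 was always named. Also named were the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold, with a mean log2 CPM of at least 3 and with every HER2 library outside the range of the GFP libraries. From each list up to 4 members with the smallest p could be named. Members outside this rule were named where 5 or fewer passed in a direction, and the text says that they were chosen after their values were seen.

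Expected counts were rounded and fitted in the same way on 16 libraries, without the GFP 11 column, which repeats another column. Correlations between pipelines are across genes. Within-group spread was the median over genes of the absolute deviation of log2(value + 1) from the group mean, for TPM and for the normalised signal scaled to the same total, over genes with a mean TPM of at least 1. The held-out signature refitted the model without each library in turn and took 100 genes per direction by p.

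Alternatives included DESeq2 1.42.0 size factors and its Wald test, library size without TMM, limma-voom, no filter and a filter of 5 CPM in 5 libraries, controls of 1 lane, the replicate number or the index as a block, limma-trend on TPM and FPKM, expected counts, and each replicate left out. Chosen after the data were seen were a keratinocyte differentiation score as a covariate, fits without GFP 5 and GFP 6 or without GFP 2 and GFP 11, controls of 1 lane without GFP 2 or GFP 11, fits on the 13 libraries with intact columns in the second pipeline, a signature without ERBB2, lists with library size alone as the scaling, lists with each replicate left out, and expected counts with each HER2 replicate left out.

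The steps were tested on simulated data with 200 changed genes, 3 times. At 1.5-fold and 2-fold, 82.9% and 96.3% of changed genes were recovered for HER2 against GFP, with 3.62% of calls false, 84% and 97% for the GFP lanes, with 4.8% false, and 35.2% and 74% for expected counts, with 4.94% false. A list raised 1.5-fold was called by camera in 3 of 3 simulations, with 1 call among the other lists. The simulated genes were drawn independently of each other, without structure of lane or culture. These rates therefore hold for such data only and do not test the preset correlation. Pairs of libraries were checked for duplication by the scatter of their counts, with a chi-square per degree of freedom of at least 1.98 within GFP and 2.91 within HER2, where 1 is counting error alone, so that none repeated another.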

Results

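The data were poly(A)-selected RNA sequencing profiles of human mammary epithelial cells (HMEC), cells grown from the lining of the breast, 18 hours after infection with adenovirus at a multiplicity of infection of 500. The virus carried either ERBB2, the gene for the receptor tyrosine kinase HER2 (5 libraries, named HER2 1 to 5 after the sample titles; in the deposited columns HER2 4 and HER2 5 are HER2-5 and HER2-6, and there is no HER2-4), or green fluorescent protein as the control (12 libraries, named GFP 1 to 12). Read counts per gene summed to 17.5 M ± 3.3 (SD, n = 12; M stands for 1000000) in GFP and 20.9 M ± 3.27 (SD, n = 5) in HER2, which did not differ in a two-sided exact permutation test (p = 0.0711). The totals of GFP 1 to 12 were, in M counts, 16.9, 16.6, 14.7, 17.8, 21.2, 13.6, 18.4, 15.9, 19.5, 16.5, 25.1 and 13.5. Those of HER2 1 to 5 were 23, 21.2, 23.3, 21.6 and 15.2. The 10 most abundant genes of each library took 13.3% ± 0.825 (SD, n = 12) of counts in GFP and 14.5% ± 0.458 (SD, n = 5) in HER2 (exact permutation p = 0.0108). GFP 1 to 6 were sequenced in lane 1, GFP 7 to 12 in lane 2 and all HER2 libraries in lane 4, so that lane and virus cannot be separated. The labels do not say whether the libraries of a group came from separate cultures, and every p-value measures only the spread between these libraries.

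The comparison of HER2 with GFP asked which transcripts change downstream of ERBB2 overexpression. Gene counts do not tell transcripts of the viral insert from those of the cells' own ERBB2 gene. Counted together, ERBB2 (chromosome 17, 37844167 to 37886679, plus strand, GRCh37) rose 53.5-fold, from 167 ± 9.34 counts per 1000000 (CPM; SD, n = 12) to 8927 ± 746 CPM (SD, n = 5). Its log2 fold change was 5.74 (SE 0.0563, edgeR adjusted p = 1.25e-25), and its share of all counts went from 0.0169% ± 0.000769 (SD, n = 12) to 0.862% ± 0.0732 (SD, n = 5). Around it, heat shock, interferon response and NF-kB genes were lower with HER2, while genes of ERK signalling output, cell division and the endoplasmic reticulum were higher, as lists in camera with a preset correlation between genes. With an estimated correlation the heat shock list alone passed. Most of these changes were small: the median size of a called change was 0.295 on the log2 scale. Of 13917 genes tested, 2669 passed an adjusted p of 0.05 in edgeR, 1360 of them higher and 1309 lower with HER2, and 112 also changed at least 2-fold, 22 higher and 90 lower. The groups did not overlap for 793 of the called genes, where chance would give 0.0323% of the genes tested.

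**Figure D1:**
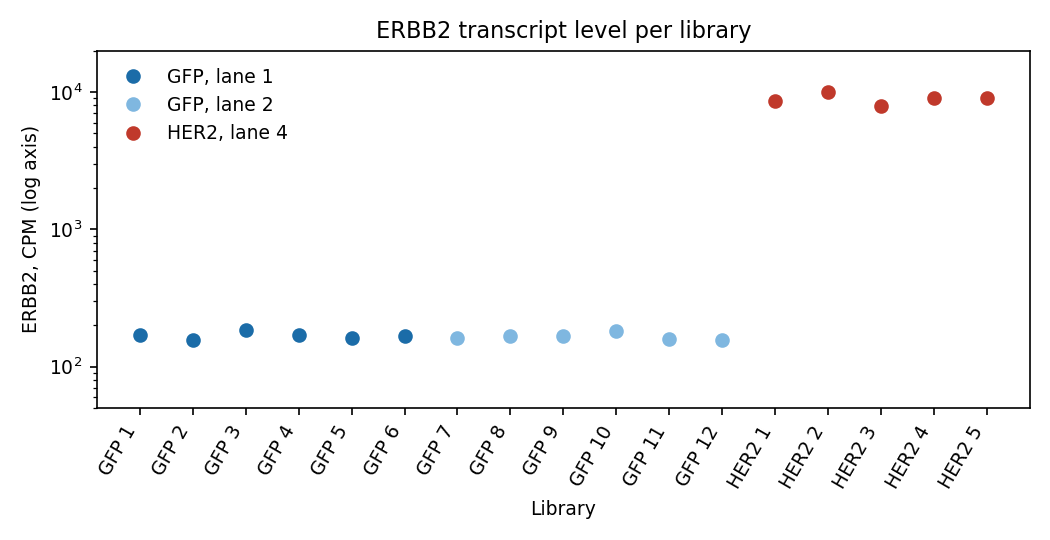
ERBB2 transcript level (CPM, log axis) in each of the 17 libraries, 1 point per library, coloured by virus and sequencing lane. The GFP libraries averaged 167 and the HER2 libraries 8927 CPM.

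With library size alone as the scaling, 3637 genes passed, of which 21.3% were higher with HER2, against 51% with TMM, and the median of all tested genes moved from -0.01 to -0.08 on the log2 scale. Lists moved with it, and 16 of 33 passed. Endoplasmic reticulum stress had 5 higher and 0 lower (median 0.14), glycolysis and hypoxia 5 and 2 (0.10) and mesenchymal markers 3 and 0 (0.10). TGF-beta and BMP targets had 3 and 2 (0.07) and integrins and laminins 4 and 0 (0.07). G2/M genes had 14 and 0 (0.25) and immediate early genes 3 and 3 (-0.08). Luminal markers had 7 higher and 2 lower (median 0.02). Keratinocyte differentiation (adjusted p = 0.21) and a list of histones and nuclear noncoding RNA (0.0541) did not pass. Against the 6 GFP libraries of lane 2 alone 1611 genes passed, and against those of lane 1 alone 3564 passed.

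Beyond ERBB2, the largest rises among well expressed genes whose groups did not overlap were found in PNMA2 (2.88-fold, 5.9 to 17 CPM), ATP6V0A4, a proton pump subunit (2.22-fold), CTGF, a secreted target of TGF-beta and YAP signalling (2.03-fold), and MAP1B, which binds microtubules (1.94-fold). STC1, a secreted glycoprotein, rose 1.91-fold, RPSAP52 1.84-fold, the simple-epithelial keratin KRT18 1.83-fold, MYADM 1.83-fold and the adaptor gene SHC4 1.8-fold. Their adjusted p ran from 8.99e-11 for MYADM to 3.85e-05 for CTGF. Among the falls, HSPA6, a heat-inducible chaperone, was 6.61-fold lower (95.1 ± 14.3 CPM, SD, n = 12, to 14.4 ± 1.36 CPM, SD, n = 5). DNAJA4, another chaperone gene, was 3.1-fold lower. The interferon-induced genes IFIT1, MX1, IFI6 and IFI44 were 4.39-fold, 3.21-fold, 2.84-fold and 2.53-fold lower. CFB, the complement factor B gene, was 2.82-fold lower, TNFAIP2 2.73-fold, the acute phase gene SAA2 2.42-fold and EPGN, a ligand of the EGF receptor, 2.34-fold. The adjusted p of these falls ran from 5.06e-13 for HSPA6 to 0.000904 for IFI6. Reads of HSPA6 and of SAA2 may be shared with their near-identical neighbours, since the handling of such reads was not stated. The value of RPSAP52, a pseudogene, is uncertain for the same reason.

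Heat shock genes fell together. Of 13 chaperone genes tested, 11 fell and 0 rose (11 and 0 adjusted over the list alone), with a median of -0.45 on the log2 scale. HSPA1A and HSPA1B, the inducible HSP70 genes, whose near-identical sequences share reads, were 2.32-fold and 2.22-fold lower, and HSPH1, an HSP70 cochaperone, was 1.44-fold lower. The list passed in camera (adjusted p = 2.08e-16; adjusted p = 0.0266 with an estimated correlation), and it was the 1 list of 33 to pass with that setting. All 5 HER2 libraries scored below every GFP library, from -0.69 to -0.60 against -0.09 to 0.16 (exact permutation p = 0.000162, the smallest the design allows). The median was -0.44 against the GFP libraries of lane 2 and -0.43 against those of lane 1.

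NF-kB targets and cytokines fell: 10 of 23 were lower and 1 higher (11 and 1 adjusted over the list alone). TNFAIP2, SOD2, the mitochondrial superoxide dismutase gene, and the chemokine genes CXCL5 and CCL20 were 2.73-fold, 1.86-fold, 1.85-fold and 2.98-fold lower, while NFKB2, named after its values were seen, was 1.15-fold higher. The list passed in camera with a median of -0.17 (adjusted p = 0.000186; adjusted p = 0.0514 with an estimated correlation), and all 5 HER2 libraries scored below every GFP library. The NFKB2 call ended without HER2 2, HER2 4 or HER2 5 (adjusted p up to 0.0661) and against the GFP libraries of lane 2.

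Interferon response genes showed the largest fall of any list. Of 32 tested, 30 were lower and 0 higher (31 and 0 adjusted over the list alone), with a median of -0.87. BST2, which tethers virus particles, was 2-fold lower, PARP9 1.77-fold, IFI44L 2.95-fold and IFIT5 1.43-fold. The list passed in camera (adjusted p = 2.08e-16; adjusted p = 0.194 with an estimated correlation). All 5 HER2 libraries scored below every GFP library, from -1.09 to -0.82 against -0.51 to 0.55 (exact permutation p = 0.000323). Its size depended on the control: the median was -1.15 against the GFP libraries of lane 1 and -0.51 against those of lane 2, where 19 of 29 tested members were lower. Within GFP the list differed between the lanes themselves, with a median of -0.58 for lane 2 over lane 1.

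**Figure D2:**
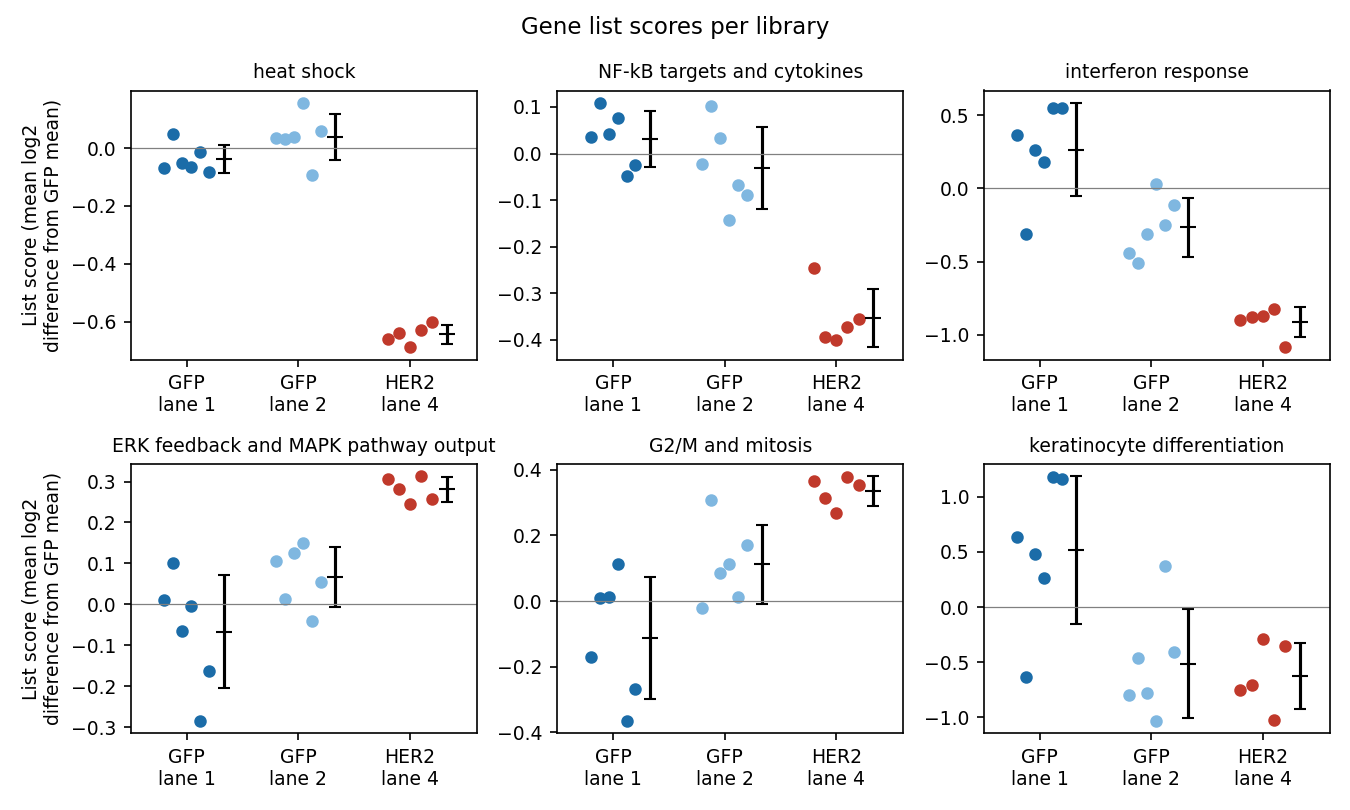
Scores of 6 gene lists (mean log2 difference of the list's genes from the mean of the 12 GFP libraries), 1 point per library, for the 6 GFP libraries of lane 1, the 6 of lane 2 and the 5 HER2 libraries of lane 4. Bars give the mean and SD of each set, and the HER2 heat shock scores lay between -0.69 and -0.60 while the keratinocyte differentiation scores of HER2 lay inside the range of the GFP libraries.

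ERK feedback and MAPK pathway output genes rose: 12 of 18 were higher and 1 lower (15 and 1 adjusted over the list alone), with a median of 0.32. The early response gene IER3 was 1.39-fold higher, DUSP4, a phosphatase that switches off ERK, 1.49-fold, and the transcription factor gene ETV4 1.33-fold. The ephrin receptor gene EPHA4 was 1.71-fold lower. The list passed in camera (adjusted p = 7.08e-08; adjusted p = 0.193 with an estimated correlation), and all 5 HER2 libraries scored above every GFP library. It passed against the GFP libraries of either lane, with medians of 0.39 for lane 1 and 0.29 for lane 2. Lane 2 over lane 1 within GFP gave 0.17.

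Cell division genes rose. Of 25 G2/M and mitosis genes, 19 were higher and 0 lower (23 and 0 adjusted over the list alone), with a median of 0.32 (adjusted p = 4.64e-11; adjusted p = 0.194 with an estimated correlation). The mitotic kinase gene PLK1 was 1.49-fold higher, CDC20, an activator of the anaphase-promoting complex, 1.36-fold, DLGAP5 1.34-fold and CDK1 1.32-fold. Against the GFP libraries of lane 2 the median was 0.21, with 8 members higher, and against those of lane 1 it was 0.45, with 23 higher. Lane 2 over lane 1 within GFP gave 0.21 as well. Of 25 G1/S and DNA replication genes, 10 were higher and 0 lower (13 and 1 adjusted over the list alone), with a median of 0.21 (adjusted p = 4.51e-05; adjusted p = 0.194 with an estimated correlation). MCM10, a replication factor, was 1.46-fold higher, RRM2, a subunit of ribonucleotide reductase, 1.32-fold, UNG 1.16-fold and MCM4 1.14-fold. Against the GFP libraries of lane 2, 5 G1/S members were higher, and library size alone as the scaling gave 4 higher and 1 lower (median 0.14).

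Endoplasmic reticulum stress genes rose, with 10 of 17 higher and 0 lower (11 and 0 adjusted over the list alone) and a median of 0.21 (adjusted p = 2.34e-07; adjusted p = 0.194 with an estimated correlation). HERPUD1, which acts in the disposal of misfolded proteins, was 1.35-fold higher, the chaperone gene DNAJB9 1.31-fold and SEC24D, a coat protein of transport vesicles, 1.28-fold. Against the GFP libraries of lane 2, 4 members were higher. Of 22 genes of glycolysis and the hypoxia response, 11 were higher and 1 lower (14 and 2 adjusted over the list alone), with a median of 0.18 (adjusted p = 0.000394; adjusted p = 0.194 with an estimated correlation). PFKP, PDK1, LDHA and PGK1, enzymes of glucose breakdown or its control, were 1.3-fold, 1.24-fold, 1.19-fold and 1.18-fold higher. ADM, a hypoxia-induced peptide gene named after its values were seen, was 1.37-fold lower. The p53 targets went down, with 7 of 25 lower and 1 higher (12 and 1 adjusted over the list alone) and a median of -0.13 (adjusted p = 0.00195; adjusted p = 0.0686 with an estimated correlation). XPC, a DNA repair gene, SESN2, FDXR and C12orf5 were 1.26-fold, 1.25-fold, 1.25-fold and 1.18-fold lower. GADD45A, the 1 member that rose (1.14-fold, named after its values were seen), did not pass without HER2 5 (adjusted p = 0.0581) or against the GFP libraries of lane 2 (0.079), and with library size alone 13 p53 targets were lower and 0 higher (median -0.20).

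Markers of cell identity moved in several directions. Of 20 luminal epithelial markers, 7 were higher and 1 lower (7 and 1 adjusted over the list alone), with a median of 0.09 (adjusted p = 0.00961; adjusted p = 0.243 with an estimated correlation). The luminal keratin genes KRT18, KRT8 and KRT19 were 1.83-fold, 1.63-fold and 1.62-fold higher, and ESR1, the oestrogen receptor gene, was 1.73-fold lower. The list did not pass against the GFP libraries of lane 1 (adjusted p = 0.208, median -0.05) and did against those of lane 2 (adjusted p = 1.08e-05). Of 8 myoepithelial contractile markers, 4 were higher and 1 lower (6 and 1 adjusted over the list alone), with a median of 0.32 (adjusted p = 0.00316; adjusted p = 0.205 with an estimated correlation). CNN1, ACTG2 and TAGLN, which encode parts of the contractile machinery, were 2.01-fold, 1.64-fold and 1.42-fold higher, TPM2, named after its values were seen, was 1.23-fold higher, and the oxytocin receptor gene OXTR was 2.65-fold lower. Lane 2 over lane 1 within GFP gave a median of 0.29 for this list. Of 15 mesenchymal transition markers, 5 were higher and 0 lower (7 and 0 adjusted over the list alone), with a median of 0.17 (adjusted p = 0.000986; adjusted p = 0.193 with an estimated correlation). The intermediate filament gene VIM was 1.71-fold higher, S100A4 1.47-fold, ITGA5 1.23-fold, AXL 1.16-fold and SNAI2, named after its values were seen, 1.09-fold. The 15 also include the epithelial cadherin gene CDH1, for which a fall would mark such a transition, and it was called in neither direction. The AXL call ended without HER2 4 (adjusted p = 0.0548), and that of SNAI2 ended in 11 of the 17 fits that left out 1 library (adjusted p up to 0.116). Neither AXL nor SNAI2 passed against the GFP libraries of lane 2 (adjusted p = 0.094 and 0.133).

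Of 16 basal epithelial markers, 3 were higher and 0 lower (3 and 1 adjusted over the list alone), and the list did not pass (adjusted p = 0.852), with a median of -0.03 and a mean of 0.00. Library size alone gave 3 higher and 4 lower. The 3 were ITGB4, LAMA3 and LAMB3, which anchor basal cells to the basement membrane (1.31-fold, 1.25-fold and 1.2-fold higher). None of the 3 passed against the GFP libraries of lane 2, and LAMB3 did not pass without HER2 1 or HER2 2 (adjusted p up to 0.0645). Of 14 integrins and laminins outside that list, 5 were higher and 0 lower (6 and 0 adjusted over the list alone), with a median of 0.14 (adjusted p = 0.00228; adjusted p = 0.497 with an estimated correlation). They were ITGA2 (1.37-fold), ITGB6 (1.24-fold), ITGB5 (1.15-fold), the matrix protein gene THBS1 (1.49-fold) and, named after its values were seen, ITGA3 (1.17-fold). ITGB6 did not pass without HER2 1 (adjusted p = 0.0543), while THBS1 and ITGA3 lost their calls in 7 and 11 of the 17 fits that left out 1 library (adjusted p up to 0.0966 and 0.103). Against the GFP libraries of lane 2, 1 member passed.

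Keratinocyte differentiation genes were lower, with 6 of 17 lower and 0 higher (9 and 0 adjusted over the list alone) and a median of -0.71 (adjusted p = 0.0188; adjusted p = 0.634 with an estimated correlation). S100A8 and S100A9, which encode the subunits of calprotectin, were 1.96-fold and 1.63-fold lower, SBSN 2.38-fold and TGM1, an enzyme that crosslinks the skin barrier, 1.56-fold. The fall rested on the controls of lane 1: 13 members were lower against those and 0 against those of lane 2 (median -0.15, adjusted p = 0.76), and 0 of the 5 HER2 libraries scored below every GFP library. SBSN did not pass without HER2 4 (adjusted p = 0.0579), nor TGM1 without HER2 1 (adjusted p = 0.0537).

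**Figure D3:**
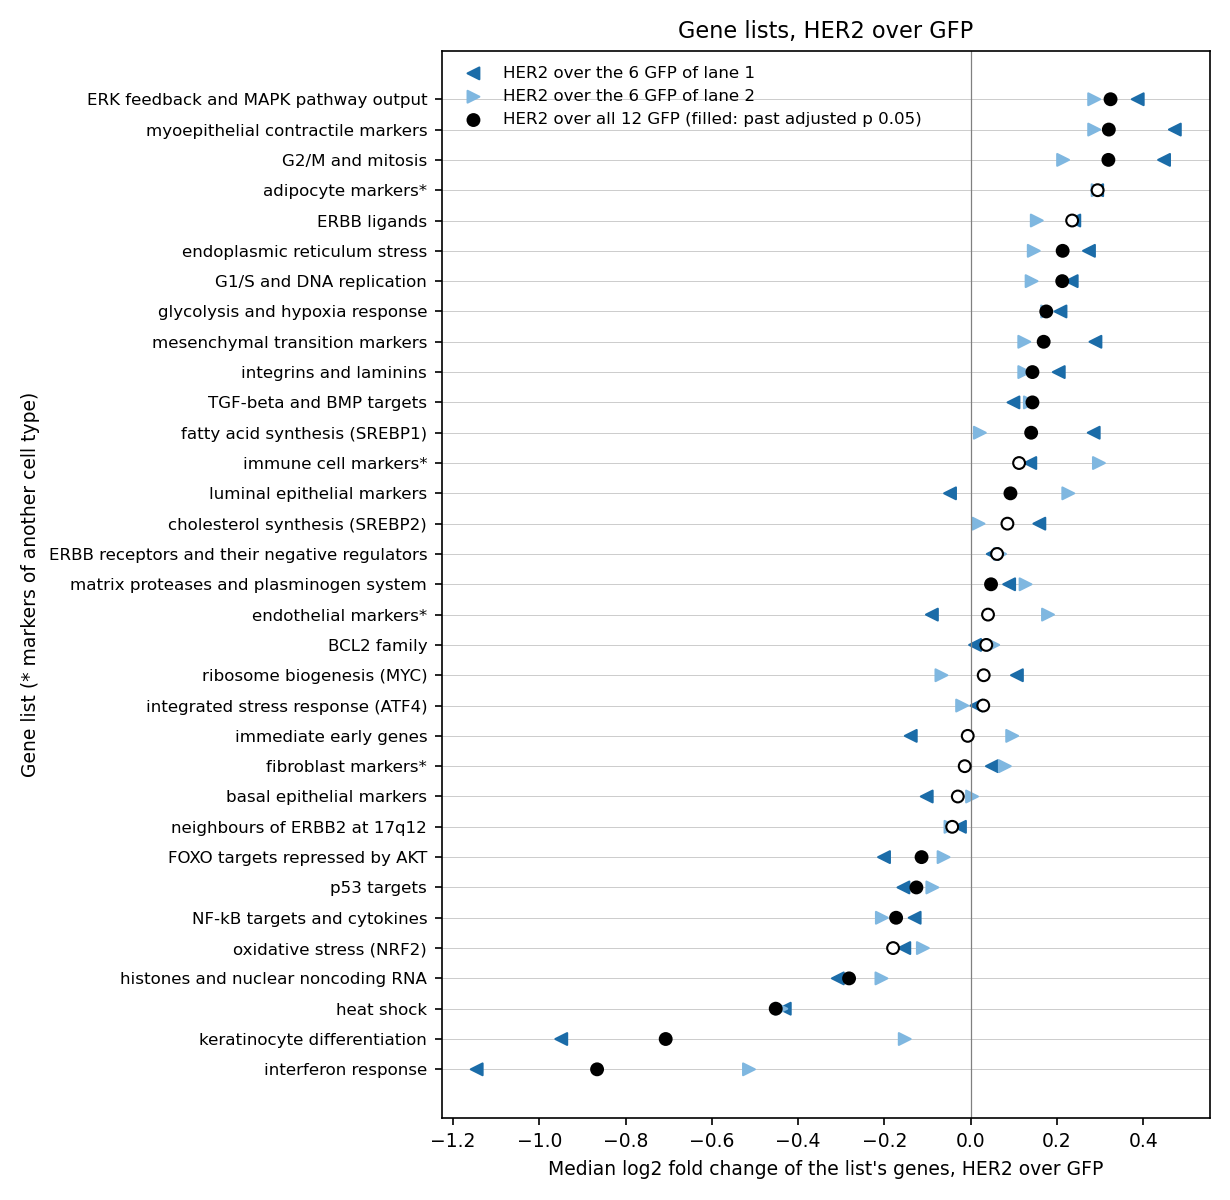
Median log2 fold change, HER2 over GFP, of the genes of each of the 33 lists, against all 12 GFP libraries (circles, filled where the list passed an adjusted p of 0.05 in camera) and against the 6 GFP libraries of lane 1 or of lane 2 alone (triangles). Keratinocyte differentiation went from -0.95 against lane 1 to -0.15 against lane 2, while heat shock stayed at -0.43 and -0.44.

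Genes of matrix turnover split. Of 19 matrix proteases and plasminogen system genes, 8 were higher and 5 lower (9 and 5 adjusted over the list alone), with a median of 0.05 that was -0.02 with library size as the only scaling (adjusted p = 0.0278; adjusted p = 0.243 with an estimated correlation). The plasminogen activator genes PLAT and PLAU and the urokinase receptor gene PLAUR were 1.69-fold, 1.48-fold and 1.53-fold higher, and TIMP3, an inhibitor of matrix proteases, was 1.21-fold higher. The 5 lower genes, named after their values were seen, were the collagenase and other metalloproteinase genes MMP3 (2.09-fold), MMP13 (1.85-fold), MMP1 (1.45-fold) and MMP9 (1.37-fold) and their inhibitor gene TIMP1 (1.3-fold). Of these, MMP13 passed against the GFP libraries of lane 2. The MMP9 call ended without HER2 4 or HER2 5 (adjusted p up to 0.0655), that of MMP1 in 11 of the 17 fits that left out 1 library (up to 0.136), and that of the list without GFP 10 (0.0551) or HER2 1 (0.0699) and against the GFP libraries of lane 1 (0.496). Of 14 TGF-beta and BMP targets, 4 were higher and 1 lower (8 and 2 adjusted over the list alone), with a median of 0.14 (adjusted p = 0.0278; adjusted p = 0.194 with an estimated correlation). CTGF, PMEPA1, BMP2 and BHLHE40 were 2.03-fold, 1.31-fold, 1.2-fold and 1.13-fold higher, and ID2, named after its values were seen, was 1.59-fold lower. The list did not pass against the GFP libraries of lane 1 (adjusted p = 0.132) or without HER2 1 (0.0593), and ID2 did not without HER2 1 or HER2 4 (up to 0.0606) or against the GFP libraries of lane 2 (0.125).

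Around the receptor itself, 4 of 10 ERBB ligands were higher and 2 lower (4 and 2 adjusted over the list alone), and the list did not pass (adjusted p = 0.334; median 0.24, mean -0.01). HBEGF and TGFA were 1.35-fold and 1.24-fold higher, as were, named after their values were seen, EGF (1.53-fold) and NRG1 (1.27-fold). EPGN and NRG2 were 2.34-fold and 1.96-fold lower. EGF, NRG1 and NRG2 did not pass against the GFP libraries of lane 2, and the NRG1 call ended in 11 of the 17 fits that left out 1 library (adjusted p up to 0.109). Of 16 ERBB receptors and their negative regulators, 7 were higher and 1 lower (7 and 2 adjusted over the list alone; adjusted p = 0.0709, 0.0447 without HER2 4, and 0.000967 in fry). CBLC and PTPN12, which restrain the receptors, were 1.37-fold and 1.2-fold higher. LRIG3 was 1.23-fold higher and the cytokine inhibitor gene SOCS3 1.29-fold lower. The median of this list was 0.06 and turned to -0.01 with library size alone, which gave 4 higher and 3 lower. Among 13 neighbours of ERBB2 on chromosome 17, 1 was higher and 0 lower (0 and 0 adjusted over the list alone; adjusted p = 0.751; median -0.04), and with library size alone 0 were higher and 4 lower (median -0.12). The 1 higher gene was the adaptor gene GRB7 (1.24-fold, adjusted p = 0.0425), whose call ended in 12 of the 17 fits that left out 1 library (adjusted p up to 0.115) and against the GFP libraries of lane 1 (0.325). Of 24 immediate early genes, 4 were higher and 2 lower (4 and 2 adjusted over the list alone; adjusted p = 0.519; median -0.01, test upward). KLF6, CYR61, NR4A2 and SRF were 1.35-fold, 1.43-fold, 1.49-fold and 1.15-fold higher, and ATF3 and BTG2, named after their values were seen, were 1.36-fold and 1.38-fold lower. ATF3, BTG2 and SRF (adjusted p = 0.102, 0.124 and 0.0641) did not pass against the GFP libraries of lane 2, where the list passed upward (adjusted p = 0.0148), and BTG2 did not without HER2 2 or HER2 4 (adjusted p up to 0.0623).

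Of 22 FOXO targets repressed by AKT, 4 were lower and 1 higher (9 and 2 adjusted over the list alone), with a median of -0.11 (adjusted p = 0.0214; adjusted p = 0.566 with an estimated correlation). BCL2L11, FBXO32 and SESN1 were 1.49-fold, 1.36-fold and 1.31-fold lower, as was FOXO1, named after its values were seen (1.25-fold), which did not pass against the GFP libraries of lane 2 (adjusted p = 0.111). IRS2, an insulin receptor adaptor, was 1.25-fold higher. The list did not pass without HER2 5 (adjusted p = 0.0627), against the GFP libraries of lane 2 (0.367) or with library size alone (0.0541), where 9 members were lower and 1 higher (median -0.19). Of 13 genes of fatty acid synthesis, 1 was higher and 0 lower (1 and 0 adjusted over the list alone), with a median of 0.14 (adjusted p = 0.0291; adjusted p = 0.634 with an estimated correlation). The 1 gene was MID1IP1 (1.19-fold), whose call ended without HER2 3, HER2 4 or HER2 5 (adjusted p up to 0.0769), against the GFP libraries of lane 2 (0.188) and with library size alone, which left 0 members called. The list lost its call without GFP 5 (adjusted p = 0.0795), GFP 6 (0.0649), GFP 11 (0.0507) or HER2 1 (0.0564) and against the GFP libraries of lane 2 (0.76, median 0.02). Of 25 genes of cholesterol synthesis, 1 was higher and 1 lower (1 and 1 adjusted over the list alone; adjusted p = 0.18; median 0.09), IDI1 at 1.22-fold higher and TM7SF2 at 1.33-fold lower, and library size alone gave 1 higher and 4 lower. Against the GFP libraries of lane 1 this list passed with 10 members higher and 1 lower (adjusted p = 0.00446).

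Among the 33 lists, 19 passed in camera with a preset correlation of 0.01, 12 upward and 7 downward. With an estimated correlation 1 passed, and 18 passed in fry, where fatty acid synthesis (adjusted p = 0.227), keratinocyte differentiation (0.263), FOXO targets (0.0753) and integrins and laminins (0.0557) did not. A list of replication-dependent histones and nuclear noncoding RNA passed as well: 3 of 8 were lower and 0 higher (4 and 0 adjusted over the list alone). Its median was -0.28 (camera adjusted p = 0.0115, and 0.194 with an estimated correlation). The list was meant as a sign of RNA quality, on the view that poly(A) selection leaves little of these transcripts. Its member NEAT1 stood at 455 CPM in GFP and 359 CPM in HER2, so that reading is uncertain. HIST2H2BE, HIST1H2AC and HIST1H2BD were 1.32-fold, 1.37-fold and 1.3-fold lower, the last with its call ended in 10 of the 17 fits that left out 1 library (adjusted p up to 0.111). The groups overlapped in this score: HER2 2 was at 0.118 and the other HER2 libraries lay from -0.359 to -0.207, while the GFP libraries spanned -0.295 to 0.325. Against the GFP libraries of lane 2, 1 member was lower.

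The comparison of the GFP libraries of lane 2 with those of lane 1 measured how far cells with the same virus differed, since HER2 had a lane of its own. In camera 18 of 33 lists passed between these lanes, against 19 between HER2 and GFP, and with an estimated correlation 0 passed. Interferon response and keratinocyte differentiation genes were lower in lane 2 as sets, with medians of -0.58 and -0.81, of which 27 of 31 and 16 of 17 members had an unadjusted p under 0.05. Ribosome biogenesis genes (median 0.18), G2/M genes (0.21) and genes of cholesterol synthesis (0.13) were higher in lane 2, as were genes of fatty acid synthesis (0.22). These 6 lists had the smallest p in camera (adjusted p = 2.46e-18, 1.31e-11, 4.59e-09, 1.65e-08, 4.54e-06 and 2.98e-07; adjusted p = 0.295, 0.295, 0.295, 0.295, 0.313 and 0.295 with an estimated correlation). FOXO targets (adjusted p = 3.92e-05) and immediate early genes (5.4e-05) also passed, lower in lane 2, and myoepithelial markers (0.000579), G1/S genes (0.00187), ERK output (0.00363) and endoplasmic reticulum stress (0.00856), higher in lane 2 (adjusted p = 0.295, 0.295, 0.295, 0.295, 0.378 and 0.499 with an estimated correlation). Mesenchymal markers (median 0.083, camera adjusted p = 0.0243) and integrins and laminins (0.076, 0.0317) passed higher in lane 2, the direction seen with HER2. Basal markers (-0.111, 0.00917), matrix proteases (-0.055, 0.0099) and luminal markers (-0.137, 0.0172) passed lower in lane 2. Gene by gene, edgeR called 0 of 13621 genes, with 2634 (19.3%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.0884. DESeq2 called 372, and edgeR called 2631 without GFP 2 and GFP 11, a fit chosen after the data were seen. Heat shock genes passed as well, higher in lane 2 and so opposite to their fall with HER2 (median 0.09, adjusted p = 0.0134; adjusted p = 0.378 with an estimated correlation), and NF-kB targets did not (median -0.04, adjusted p = 0.531).

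The series also holds expected counts of the same libraries from a second pipeline, and the next comparison asked whether the choice of pipeline changes the contrast. Expected counts of 16 libraries gave 1704 genes past an adjusted p of 0.05 in edgeR, 1212 higher and 492 lower with HER2. The balance of directions depended on the scaling: with library size alone 1120 passed, 247 higher and 873 lower. The count also depended on single libraries, with 367 genes without HER2 4, 399 without HER2 2 and 3118 without HER2 1. ERBB2 stood at 6.11 on the log2 scale (adjusted p = 1.07e-12). Across 12687 genes tested in both, which are not independent replicates, the fold changes of the pipelines correlated with a Pearson r of 0.686 and a Spearman rho of 0.573. In both, 1017 genes passed in the same direction. Independence would give 334, but the pipelines share the same libraries, so a larger overlap was given by the design. Of the 2669 genes called from counts, 373 had the opposite sign with expected counts. In the lists, ERK feedback and MAPK pathway output (adjusted p = 0.743), TGF-beta and BMP targets (0.547), luminal (0.11) and myoepithelial (0.11) markers, keratinocyte differentiation (0.0797), fatty acid synthesis (0.0776) and matrix proteases (0.0597) did not pass with expected counts. Immediate early genes passed downward (adjusted p = 0.0412) and ribosome biogenesis upward (adjusted p = 0.0062). The fit on 16 libraries behind these signs and lists holds the HER2 2 and HER2 4 columns, which lost most of their counts, as described next. The lists were not tested without those columns, so these list changes cannot be credited to the choice of pipeline.

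The columns of 4 libraries in the second pipeline differed from the rest. The GFP 11 column equalled the GFP 10 column in 20501 of 20501 genes and was left out of these comparisons. The GFP 12 column held 0 for all 583 genes of chromosomes 8, 9 and X with a mean count over 500, and for 0 of 5099 such genes on the other chromosomes. The HER2 2 and HER2 4 columns summed to 2.7 M and 5.19 M, 0.127 and 0.24 of the counts of the same libraries, against 0.927 to 0.977 in the 13 intact columns. Their losses depended on gene structure: in HER2 2 the median log2 ratio to counts, relative to the intact columns, was -8.41 for 76 genes with 1 exon and -2.84 for 2677 genes with 11 or more. JUN, a gene with 1 exon, had 2758 counts and 2 expected counts in HER2 2. On the 13 intact columns 1035 genes passed with expected counts and 1135 with counts of the same libraries, 913 of them shared in the same direction, and r across genes was 0.975.

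**Figure D4:**
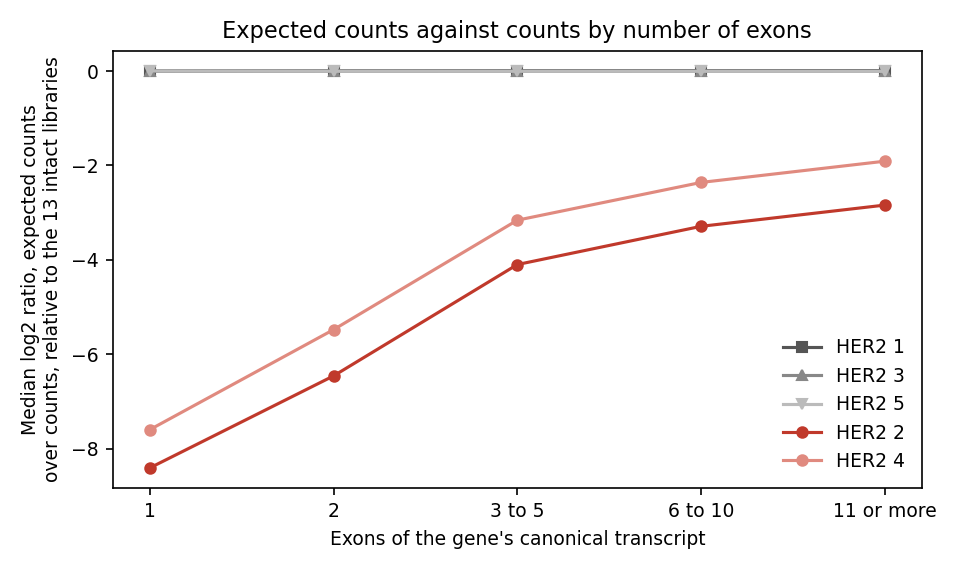
Median log2 ratio of expected counts to counts, relative to the 13 intact libraries, by the number of exons of each gene's canonical transcript, for the 5 HER2 libraries. HER2 2 went from -8.41 for 1 exon to -2.84 for 11 or more and HER2 4 from -7.6 to -1.91, while the others stayed near 0.

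Within-group spread was compared between the pipelines as the median absolute deviation of each library from its group mean on a log2 scale. It averaged 0.0845 ± 0.0209 (SD, n = 16) from TPM and 0.16 ± 0.0872 (SD, n = 16) in the second pipeline. The spread was higher there in 16 of 16 libraries (two-sided exact sign-flip permutation test, p = 3.05e-05, the smallest the design allows). That test takes the differences as independent. They are not, since the libraries of a group share a mean that the damaged columns shift, so this p-value overstates the evidence. Intact HER2 1, HER2 3 and HER2 5 went from 0.0831, 0.0537 and 0.0767 to 0.232, 0.225 and 0.225 in the second pipeline. On the 13 intact columns the mean difference was -0.0017 (exact sign-flip permutation p = 0.102).

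A signature of the contrast was built with each library left out in turn, from the 100 higher and 100 lower genes with the smallest p. On a scale where 0 is the GFP mean and 1 the HER2 mean, the left-out GFP libraries lay between -0.116 and 0.163 and the left-out HER2 libraries between 0.877 and 1.03, so that 17 of 17 lay closer to their own group. Without ERBB2 in the signature the count was 17 again.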

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

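Most tests of the 3 patterns below were chosen only after the data were seen, the covariate and the scaling of the lists included. Planned beforehand were the estimated correlation, GFP lane 2 as the control and the comparison of the GFP lanes.

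Among the 5 HER2 libraries, 1 stood apart from the other 4 by more than the critical share of their range (0.71) in 7 of 175 values examined, and chance does so in about 1 of 20 groups, which would give 8.8. HER2 5 had total counts of 15.2 M against 21.2 M to 23.3 M, and an interferon response score of -1.09 against -0.898 to -0.822. IFI44 was at 3.41 CPM in HER2 5 against 4.57 to 4.9, and AXL at 142 CPM in HER2 5 against 149.8 to 152. HER2 4 held 172 CPM of HERPUD1 against 151 to 157 and 449 CPM of IER3 against 396 to 409. SOCS3 was at 10.2 CPM in HER2 1 against 10.7 to 10.9.

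Heat shock, interferon response and NF-kB genes were lower and G2/M and ERK output genes higher with HER2. With the keratinocyte differentiation score as a covariate the medians were -0.43, -0.64, -0.22, 0.22 and 0.27. Each list passed camera with the preset correlation (with an estimated one, and no covariate, heat shock alone passed). Library size alone gave -0.52 for heat shock and -0.94 for interferon, which argues against scaling as the whole of both. Across the 12 GFP libraries the keratinocyte score correlated with interferon (Pearson r = 0.82) and G2/M (-0.74), though at -0.16 and -0.09 within lane 2. For these 2 lists the covariate argues against position along that gradient as the whole difference. Heat shock rose as that score fell (r = -0.81) and NF-kB did not follow it (0.02), so the covariate had no fall to remove there. For ERK output this relation was not examined. GFP lane 2 over lane 1 gave 0.093 for heat shock and -0.036 for NF-kB, which argues against a difference of that kind for both. It gave -0.58 for interferon and 0.21 for G2/M, as large as HER2 over lane 2, and 0.17 for ERK output, so for interferon and G2/M such a difference may account for much of the size and for ERK output it is undecided. Even so, all 5 HER2 libraries scored below every GFP library of either lane for interferon, and 4 of 5 above every one for G2/M. An effect of lane 4 cannot be told apart from HER2, since 0 GFP libraries were in that lane. The same holds for anything else in the virus stock, infection or library preparation that differed between the groups. An effect of HER2 itself stays open as the biological hypothesis.

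The GFP libraries differ along a structure that crosses the lanes, though not as 2 clean sets. GFP 12 sided with neither, with a mean correlation of -0.15 with lane 1 and -0.041 with lane 2. Of 100 splits of the 12 GFP libraries into groups of 6, 1 called 3608 genes where the lanes called 0, which points to a structure of the samples, and it equals the lane split with GFP 2 and GFP 11 exchanged. These are also the 2 libraries of 12 whose profiles correlated better with the other lane than with their own, and among 36 exchanges of 1 library per lane none called more (the next, GFP 3 with GFP 11, called 996, so that a first form of the test, over 5 times any other, was not met). Depth is argued against by a Spearman correlation of 0.1 in size between total counts and the first principal component of the GFP libraries, but an exchange in handling and a real difference between cultures cannot be separated, and no biological explanation was tested. The keratinocyte differentiation genes, lower with HER2, may follow this structure: 0 HER2 libraries lay below every GFP library, and the GFP lanes differed by -0.81, more than HER2 from lane 2.

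In the second pipeline, the 583 expressed genes of chromosomes 8, 9 and X were all at 0 in GFP 12, which is consistent with a file that stopped after chromosome 7 in text order. In HER2 2 and HER2 4 the loss was uneven: genes with 1 exon lay -5.76 below the others on the log2 scale in HER2 2, and the loss shrank with more junctions per kilobase (Spearman 0.77 in HER2 2 and 0.78 in HER2 4). This is consistent with a step that kept mainly reads across splice junctions. A lower depth alone is argued against by the spread of the log2 ratio, an SD of 1.37 in HER2 2 against at most 0.427 in the intact columns. What produced these columns stays open, since the steps of that pipeline were not stated, and no biological explanation was tested.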

How the results depend on the processing

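Alternatives chosen after the data were seen were the covariate, lists with library size alone (16 passed), the signature without ERBB2 (17 placed), the fits without GFP 2, GFP 11 or both, without GFP 5 and GFP 6 and on the 13 libraries with intact columns, lists with 1 library left out, and expected counts with 1 HER2 library left out. The 2669 called genes stayed within 1.5 times that count except against lane 2 controls (1611), lane 1 controls without GFP 2 (4061), with expected counts (1704) and on the 13 libraries (1135). With the replicate block it was 3269, although replicate numbers do not pair the groups: profiles with the same number correlated from -0.095 to 0.14 and each HER2 library matched another number better. Leaving out 1 library gave 1984 to 2968 genes, 97 to 138 of them 2-fold, 16 to 20 lists, and ERBB2 at 5.70 to 5.78. Leaving out 1 HER2 library gave, with expected counts, 367 (without HER2 4) to 3118 (without HER2 1), with 399 without HER2 2, 3037 without HER2 3 and 2793 without HER2 5. The 112 genes past 2-fold became 187 without a filter and 51 with 5 CPM (other genes tested), 42 on TPM and 21 on FPKM, 210 with lane 1 controls (261 without GFP 2), 68 with lane 2 controls (73 without GFP 11), 198 with the replicate block, 73 with the index block and 74 with the covariate. With an estimated correlation 1 list passed instead of 19. The GFP lanes differed in 372 genes with DESeq2 and in 2631 without GFP 2 and GFP 11. With expected counts 1120 genes passed under library size alone, 247 higher and 873 lower against 1212 and 492, and 1035 on the 13 intact columns. The correlation between pipelines was 0.584 for genes with a mean log2 CPM of at least 3 and 0.975 on the intact columns, where the difference in spread reversed to -0.0017. Without HER2 2 or HER2 4 this correlation was 0.815 or 0.831, and without another HER2 library 0.603 to 0.63, so that these damaged columns account for much of its low value. For the other changes the cause was not tested. Of 4909 values of 137 called named genes under 36 alternatives, 4502 kept direction and call, 386 lost the call and 21 reversed. The reversals all came with expected counts, in a fit that holds the damaged HER2 2 and HER2 4 columns. On the log2 scale these were IER3 -0.184, KLF6 -0.139, SRF -0.153, TGFA -0.245, IRS2 -0.324, FBXO32 0.061, IDI1 -0.021, MID1IP1 -0.106, BCL2L1 -0.344, DNAJB9 -0.126, EDEM1 -0.053, TRIB3 -0.266, TIMP3 -0.246, PMEPA1 -0.24, BMP2 -0.305, BHLHE40 -0.229, GCLC 0.046, COL1A1 0.193, GADD45A -0.086, SNAI2 -0.175 and TIMP1 0.128. Some low genes had no value under the stricter filter or on FPKM, and GDF6 had none under 4 further settings. At this depth a floor of 3 counts over the group equals 0.029 CPM in HER2.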

Other observations

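Further lists did not pass as sets in camera. Of 17 NRF2 targets, which counter oxidative stress, 6 were lower and 1 higher (7 and 1 adjusted over the list alone), with a median of -0.18 (adjusted p = 0.0873, 0.00668 in fry, and 0.0433 in camera against the GFP libraries of lane 2). The haem oxygenase gene HMOX1 was 1.41-fold lower, the ferritin gene FTL 1.28-fold and GCLC, for glutathione synthesis, 1.16-fold lower, while GCLM was 1.15-fold higher, a call that ended without HER2 1 or HER2 4 (adjusted p up to 0.0667). Against the GFP libraries of lane 2, FTL (adjusted p = 0.0518) and GCLM (0.184) did not pass. Of 20 ATF4 targets of the integrated stress response, 3 were higher and 1 lower (3 and 1 adjusted over the list alone; adjusted p = 0.751; median 0.03, and -0.04 with library size alone). MTHFD2, TRIB3 and ATF4 itself were 1.22-fold, 1.21-fold and 1.11-fold higher and PSPH was 1.14-fold lower, with its call ended in 4 of the 17 fits that left out 1 library (adjusted p up to 0.0944). TRIB3 (adjusted p = 0.0977) and PSPH (0.078) did not pass against the GFP libraries of lane 2, and library size alone gave 2 members higher and 5 lower. Of 10 BCL2 family genes, 1 was higher and 1 lower (1 and 1 adjusted over the list alone; adjusted p = 0.994; median 0.04, mean -0.09, and a median of -0.04 with library size alone, which gave 0 higher and 3 lower). The survival gene BCL2L1 was 1.15-fold higher, without a call when HER2 4 or HER2 5 was left out (adjusted p up to 0.0862) or against the GFP libraries of lane 2 (0.0817), and BMF, which promotes cell death, was 2.06-fold lower. Of 18 ribosome biogenesis genes, 1 was higher and 0 lower (1 and 0 adjusted over the list alone; adjusted p = 0.402; median 0.03, and -0.04 with library size alone), the nucleolar gene NPM1 at 1.14-fold, which did not pass against the GFP libraries of lane 2 (adjusted p = 0.0728). The ribosome biogenesis list passed upward against the GFP libraries of lane 1 (adjusted p = 0.00279) and downward against those of lane 2 without GFP 11 (adjusted p = 0.00426).

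Few markers of other cell types were expressed well enough to be tested. Of 12 fibroblast markers 8 were tested, 1 higher and 1 lower (2 and 1 adjusted over the list alone; adjusted p = 0.75; median -0.01, mean 0.07). POSTN was 1.28-fold higher and COL1A1 1.21-fold lower, at 129 and 39.1 CPM in HER2, and both calls ended in 10 and 12 of the 17 fits that left out 1 library (adjusted p up to 0.134 and 0.121) and against the GFP libraries of lane 2 (0.231 and 0.212). Of 11 immune markers 3 were tested, with CD14 1.68-fold higher and CD68 1.33-fold lower (1 and 1 adjusted over the list alone; adjusted p = 0.533, and 0.0381 in fry). CD68 did not pass against the GFP libraries of lane 2 (log2 -0.21, adjusted p = 0.185). The 1 tested endothelial marker of 9, KDR, stood at 3.95 CPM in GFP and 4.03 CPM in HER2 (adjusted p = 0.871), and the 1 tested adipocyte marker of 6, LPL, at 1.35 and 1.64 CPM (adjusted p = 0.195). GDF6, a growth factor gene singled out after its values were seen, held 136 counts over the GFP libraries, 4 to 19 in each, and 0 over the HER2 libraries. Against a floor of 3 counts over the group it was at least 22-fold lower with HER2 (edgeR adjusted p = 8.52e-06).

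Other splits of the libraries asked how often a random grouping of the same sizes gives as large a result. For HER2 against GFP, 1 of 100 splits, the real one, gave 2669 genes, with 1 gene as the highest other, and 1 of 100 gave 112 genes past 2-fold, with 1 as the highest other. For expected counts, 1 of 100 gave 1704 genes, with 0 as the highest other. The real split alone gave 19 lists (1 of 100), but another gave 17, and the GFP lanes, with the same virus, gave 18, so that the number of lists says little. In the held-out signature 1 of 25 splits, the real one, placed 17 libraries, with 10 as the highest other and a median of 0. A library counted as misplaced where the fit called no gene in a direction, so this count largely repeats the number of genes called. For these results other than the number of lists, no other split drawn came near the real one. Every other split puts HER2 and GFP libraries into the same group, which raises the spread there, so low values were likely beforehand. The splits therefore do not exclude a difference of lane or culture between the groups. For the GFP lanes the real split gave 0 genes, so that 100 of 100 splits had to give as many and the count tests nothing. The highest other gave 3608, which points to a structure of the samples.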
